A study of Mus musculus with 6 samples.

How the data were processed

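RNA from skin wounds of male mice of the C57 black 6 strain was measured on 1-colour Agilent arrays, 3 from wild-type (WT) animals and 3 from FoxO1 +/- animals. Per the labels, 4 full-thickness wounds were made per mouse with a 4 mm punch, and tissue was harvested with a 6 mm punch on day 3. Cy3-labelled cRNA was prepared from 200 ng of total RNA, per the labels' protocols. The sample titles number the animals 1 to 3 within a genotype, so each array was taken as 1 animal. The series description speaks of 3 independent experiments in a way that does not say how wounds were pooled, and p-values measure the spread between these arrays.

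The deposited scanner files hold spot intensity values on a linear scale. Per the file headers, the authors extracted them with Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name version 9.1. The processed signal in them is background-subtracted and spatially detrended within an array, per the file headers, and is not scaled between arrays. Flags for outlier spots, saturated spots and spots well above background were used as deposited, per the file headers. The authors' value table holds the same processed signal rounded to 3 significant digits: all 59305 non-control spots of each array matched it within 0.6%, by feature number. It was therefore linear and not centred. Its column medians were 99.8, 103 and 112 on the WT arrays and 97.2, 98.9 and 82.4 on the FoxO1 +/- arrays. All 6 arrays lay on 1 slide and came from 1 scan. Slide row 1 held the 3 WT arrays and FoxO1 +/- replicate 1, and row 2 held FoxO1 +/- replicates 2 and 3.

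The processed signal was converted to log2, spots of a probe were averaged after outlier-flagged spots were left out, and each array's 75th percentile over non-control probes was subtracted. Levels below are therefore log2 values relative to that percentile. Each array has 62976 spots, of which 59305 are not controls, and they hold 55681 distinct probes. A total of 36 probes without an unflagged value on some array were left out. Symbols came from RefSeq accessions without their versions, matched to a mouse RefSeq gene table of a later genome assembly (GRCm38) than the array design's annotation (mm9), so that table gave symbols and each gene's chromosome, and no coordinates. Of 26392 probes with an mRNA accession, 25869 matched, and 29099 probes, 16194 of them for genomic intervals, stayed without a symbol. A probe was kept if it was well above background on every array of at least 1 genotype, which left 37898 probes, of which 21458 had a symbol. The probe with the highest mean signal stood for each gene, which left 16408 genes, 4231 of them with several kept probes. No spot was saturated. Where a probe was not well above background on any array of a genotype, only a lower bound of its fold difference is given. The bound sets the brighter group's mean against the dim group's mean of, per array, the lowest signal among probes well above background or the probe's own signal, whichever was higher.

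The comparison was FoxO1 +/- minus WT with 3 arrays per group, tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 16408 genes. Errors beside log2 differences are limma standard errors (SE). A total of 31 gene lists, fixed from textbook knowledge before the data were examined, were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation and limma's fry were run as alternatives. Of the 822 list symbols, 819 were in the reference table. An exact permutation test of 3 arrays against 3 cannot give a two-sided p under 0.1, so single values rest on limma. The precision is limited by the number of arrays. On simulated data for this comparison with 16408 genes and 3 arrays per group, 72% of 100 genes changed 2-fold and 97% of 100 genes changed 4-fold were called at an adjusted p of 0.05, with 7 false calls. Both sets were changed in the same simulated data, which eases the Benjamini-Hochberg threshold. Where fewer genes change, the threshold is stricter and these shares do not carry over. In the real data Olfr122, with a log2 difference of 2.61, had a limma adjusted p of 0.0940. A simulated list of 30 genes shifted by 0.5 was called, and 0 of 30 unshifted lists were. The simulated genes varied independently, whereas the estimated correlation ran from 0.041 to 0.83 among the lists called below. The simulation therefore cannot tell how often real lists are called falsely, and other splits of the 6 arrays called up to 15.

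The genes named were set by a rule written before the data were examined. It took Foxo1, Foxo3 and Foxo4, then the 12 higher and 12 lower genes past the adjusted threshold with non-overlapping groups. Where fewer passed, it took the smallest unadjusted p-values among genes with non-overlapping groups and at least a 1.5-fold difference, passing over clone and predicted gene names. It also took the 3 members of each list with the smallest p, a set of wound landmarks and Y-linked genes. Adipoq, Fgf2 and Notch1 were among the landmarks because they were remembered from outside these files as genes of interest to the study. Cd68, Ly6g and Xist were in the rule and were not tested here, because no probe under their symbol was kept. The alternatives covered quantile and median scaling, a percentile over detected probes, normexp background correction with an offset of 50, the authors' value table, other filters, the mean of a gene's probes, other variance models, blocks for slide row and animal number, and leaving out each array. The normexp alternative used the median spot signal with the median background, because the files have no mean spot signal. Its offset, added to every spot, by itself shrinks log2 differences of dim genes. Single values of some genes are not reported here. Figures were drawn with matplotlib 3.10.9.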

Results

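Gene expression was measured in day 3 skin wounds of 3 WT and 3 FoxO1 +/- mice, to ask how loss of 1 copy of Foxo1, a forkhead transcription factor restrained by insulin and growth factor signalling, alters the wound transcriptome. The wound site holds keratinocytes, inflammatory cells, granulation tissue and the skin around it. On the WT arrays 71.8%, 71.9% and 71.3% of spots were well above background. The values were 71.3%, 70.1% and 64.3% on FoxO1 +/- replicates 1, 2 and 3, and the 75th percentile of the signal was 899 on replicate 3 against 1095 to 1299 on the other 5 arrays. Ddx3y and Eif2s3y, genes of the Y chromosome, were well above background on all 6 arrays, and Kdm5d, another, on 3 WT arrays and 1 FoxO1 +/- array, with male given as the sex of every animal. Across genes, Pearson correlations were 0.988 to 0.992 between WT arrays, 0.991 to 0.994 between FoxO1 +/- arrays and 0.988 to 0.993 between genotypes, and these ranges overlapped. The first principal component held 33.8% of the variance and did not part the genotypes: its scores were -31.5, 12.5 and -18.9 for the WT arrays and 2.75, 10.5 and 24.7 for the FoxO1 +/- arrays. The second component, with 22.45% of the variance, did not part them either. Its scores were -20.8, 4.08 and 14.7 for WT and 18.5, 4.8 and -21.3 for FoxO1 +/- arrays. The third component, with 20.7% of the variance, put the WT arrays (1.52, -28.3 and -5.57) below the FoxO1 +/- arrays (9.17, 21.2 and 1.96). The nearest arrays there were at 1.52 and 1.96, and chance alone parts 3 arrays from 3 in 10% of cases.

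Foxo1 signal was lower in all 3 FoxO1 +/- wounds than in all 3 WT wounds on both of its probes. On the brighter probe, A_51_P138044, the level was 2.06 ± 0.26 (SD, n = 3) in WT and 1.58 ± 0.10 (SD, n = 3) in FoxO1 +/- wounds, a log2 difference of -0.48 (SE 0.14), or 0.717 of the WT level. On the probe A_52_P453884 it was 1.29 ± 0.23 (SD, n = 3) against 0.39 ± 0.10 (SD, n = 3), a log2 difference of -0.90 (SE 0.14), or 0.538 of the WT level. Neither passed limma's adjustment: the adjusted p was 0.650 over genes for the brighter probe, and 0.190 over all kept probes for the other. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 arrays allow. Where these probes lie relative to the disrupted part of the gene is not given in the sources used here. A probe outside it need not report the loss of 1 copy. How far either probe checks the genotype labels therefore stays open. The related factors Foxo3 (0.15, SE 0.12) and Foxo4 (-0.51, SE 0.33) had limma adjusted p-values of 0.920 and 0.897. A second, dimmer Foxo4 probe differed by 0.24 (SE 0.20). Leaving out single arrays gave 0.040 to 0.25 for Foxo3 and -0.73 to -0.14 for Foxo4.

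**Figure D1:**
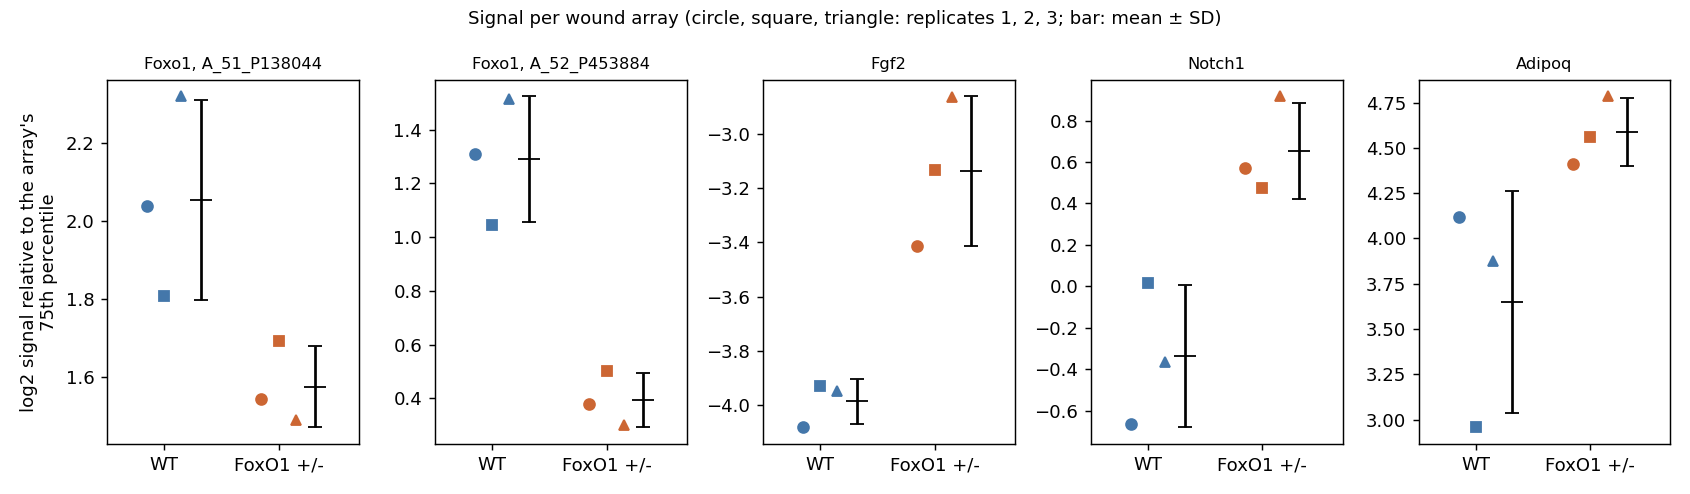
Signal of both Foxo1 probes, Fgf2, Notch1 and Adipoq on each array (y axis: log2 signal relative to the array's 75th percentile, with its own range per panel; x axis: genotype; markers: replicates; bars: mean ± SD, n = 3). In each panel the 3 FoxO1 +/- arrays lie on one side of the 3 WT arrays, and none of these genes passed the adjusted threshold.

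Of the 16408 genes tested, 1 passed an adjusted p of 0.05 in limma: Vmn1r227, a vomeronasal receptor gene, rose by 2.49 (SE 0.14, adjusted p 0.0315), from a level near background at which 1 of 3 WT arrays and 3 of 3 FoxO1 +/- arrays were well above it. With normexp background correction Vmn1r227 differed by 1.02 (limma adjusted p 0.0613). The offset of 50 in that correction by itself shrinks the differences of dim genes such as this one. At an adjusted p of 0.1 there were 5 genes, 4 higher and 1 lower. The others were the defensin gene Defb42 (1.71, SE 0.12, adjusted p 0.0620), the olfactory receptor genes Olfr1211 (3.06, SE 0.26, adjusted p 0.0845) and Olfr122 (2.61, SE 0.24, adjusted p 0.0940), and 9130409I23Rik, named after its values were seen. Olfr1211 too was near background in WT wounds, well above it on 1 of 3 WT arrays, and differed by 1.28 with normexp. 9130409I23Rik was not well above background on any FoxO1 +/- array and was at least 1.60-fold lower there (adjusted p 0.0722). Against 820 expected by chance, 1026 genes had an unadjusted limma p under 0.05, 562 higher and 464 lower. Of these, 117 differed at least 2-fold, 67 higher and 50 lower. The 3 arrays of a genotype lay entirely on one side of the other's for 1882 genes, or 11.5%, where chance gives 10%. Which genes passed the adjusted threshold changed when single arrays were left out, whereas the Vmn1r227 difference itself ran only from 2.35 to 2.57. Each such fit also has fewer arrays to estimate the spread, so a lost call need not reflect the array left out. No gene passed without WT replicate 1, WT replicate 3, FoxO1 +/- replicate 1 or FoxO1 +/- replicate 2. Without FoxO1 +/- replicate 3 the gene that passed was a different one, Olfr507, and without WT replicate 2 there were 28 genes. The count at an unadjusted p and 2-fold was 234, of which 92 were higher and 142 lower, without WT replicate 2 and 184 without FoxO1 +/- replicate 1.

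Among genes below the adjusted threshold, those with the smallest p-values and non-overlapping genotypes are given as values. Cd5l, which macrophages secrete, was at 2.32 ± 0.18 (SD, n = 3) in WT and 1.08 ± 0.12 (SD, n = 3) in FoxO1 +/- wounds, a log2 difference of -1.24 (SE 0.12, limma adjusted p 0.109). Cdhr1, Igfl3, Wfdc13, Scrg1 and Erich5 were lower by log2 differences of -1.63, -1.52, -1.12, -1.03 and -1.09. Hsd17b7, an enzyme of cholesterol synthesis, differed by -0.79 (SE 0.12) and Pdss1, an enzyme of coenzyme Q synthesis, by -0.65 (SE 0.10). Tdpoz2 was not well above background on any FoxO1 +/- array and was at least 1.47-fold lower there. Higher in FoxO1 +/- wounds were Olfr141 (1.52), Stxbp5l (0.98), Slco5a1 (0.95), Ankef1 (0.91), Clec4a2, a C-type lectin of myeloid cells (0.90), Tango6 (0.85) and Olfr1500 (0.74). Rad51ap2, not well above background on any WT array, was at least 1.97-fold higher. The limma adjusted p-values of these genes ran from 0.109 for Cd5l to 0.369 for Erich5.

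Of the 31 gene lists, 8 passed camera's adjusted p of 0.05 with the preset correlation, 4 with higher and 4 with lower members in FoxO1 +/- wounds. None passed with an estimated correlation or by fry, and at an unadjusted p under 0.05 with an estimated correlation there were 2, the sebaceous gland and the monocyte and macrophage lists. No member of any list passed 0.05 over all genes.

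Fat and skin appendage genes gave the largest list shifts. Of 28 measured adipocyte genes, 26 had higher values in FoxO1 +/- wounds, with a median log2 difference of 0.60 (camera adjusted p 4.59e-10, adjusted p = 0.957 with an estimated correlation). The examples were the hormone gene Retn (1.56, SE 0.26), Nnat (1.31, SE 0.36) and the lipase gene Lipe (0.63, SE 0.19), of which Retn was the 1 member past 0.05 adjusted over the list alone. Adipoq, which encodes adiponectin, differed by 0.94 (SE 0.31, limma adjusted p 0.700), and by 0.59 without WT replicate 2 to 1.17 without WT replicate 1. The mean of the adipocyte list was -0.78 on WT replicate 2 against -0.01 and -0.07 on the other WT arrays and 0.14 to 0.45 on the FoxO1 +/- arrays. Of 20 measured sebaceous gland genes, 17 had lower values, with a median of -0.52 (camera adjusted p 1.93e-07, adjusted p = 0.736 with an estimated correlation), and all 3 FoxO1 +/- arrays had a lower list mean than all 3 WT arrays. Adjusted over the list alone, 6 members passed 0.05, all lower. The fatty acid elongase genes Elovl3 (-1.41, SE 0.27) and Elovl6 (-1.19, SE 0.28) and the keratin gene Krt79 (-1.38, SE 0.28) had the smallest p-values. Of 36 measured hair follicle genes, 33 had lower values, with a median of -0.88 (camera adjusted p 2.94e-08, adjusted p = 0.957 with an estimated correlation), and 0 passed over the list alone. Sostdc1, an inhibitor of BMP and Wnt signals, differed by -1.04 (SE 0.20), Lef1 by -0.84 (SE 0.35) and the stem cell marker Lgr5 by -0.70 (SE 0.30). The hair follicle result rested on WT replicate 1, whose list mean was 2.49 against -0.72 to -0.28 on the other 5 arrays. Without it the median was -0.10 and the camera adjusted p 0.163. Lgr5 was highest on it and differed by -0.40 without it. Sostdc1 and Lef1 were highest on WT replicate 3 instead, and leaving out single arrays gave differences of -1.23 to -0.86 for Sostdc1 and -1.22 to -0.56 for Lef1, nearest to 0 in both without WT replicate 3.

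**Figure D2:**
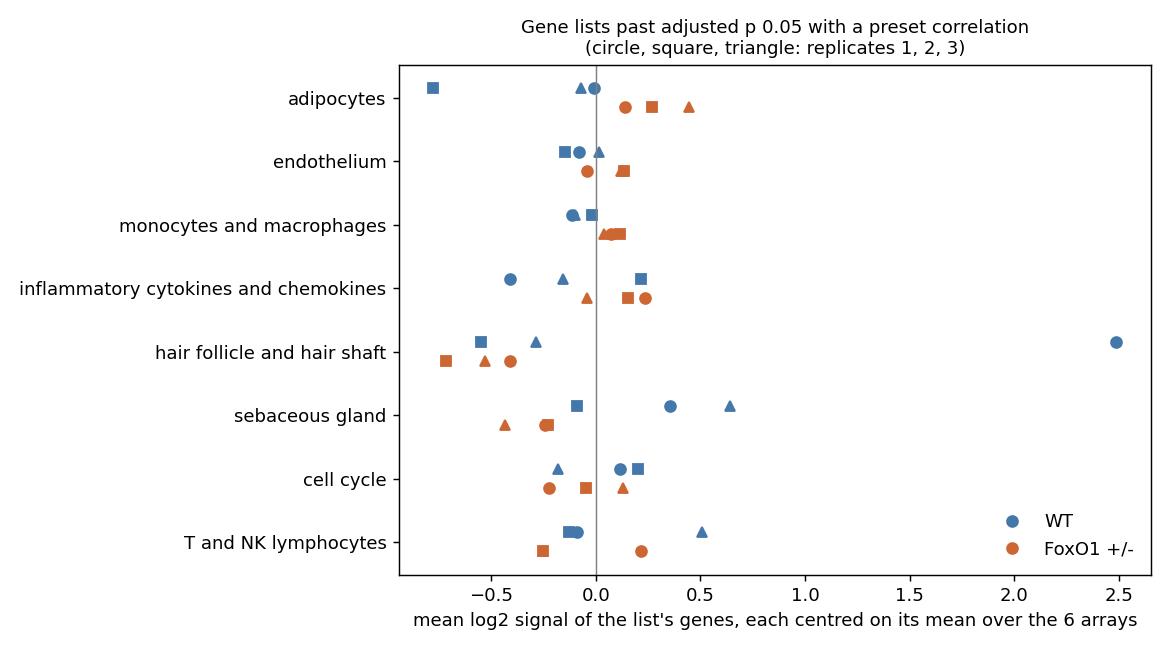
Mean log2 signal of the measured genes of the 8 lists past the adjusted threshold with the preset correlation, each gene centred on its mean over the 6 arrays (x axis), per list (y axis) and array (blue: WT, orange: FoxO1 +/-, marker shapes: replicates). WT replicate 1 stands at 2.49 for the hair follicle list and WT replicate 2 at -0.78 for the adipocyte list, and no list passed with an estimated correlation.

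Among vessel and immune cell lists the shifts were smaller. Of 27 measured endothelial genes, 24 had higher values, with a median of 0.20 (camera adjusted p 2.17e-05, adjusted p = 0.957 with an estimated correlation). Ecscr differed by 0.33 (SE 0.09) and Egfl7 by 0.28 (SE 0.10), whereas Esm1, a proteoglycan gene of activated endothelium, went the other way at -0.67 (SE 0.10) and was the 1 member past 0.05 adjusted over the list alone. Of 31 measured monocyte and macrophage genes, 26 had higher values, with a median of 0.14 (camera adjusted p 0.00134, adjusted p = 0.736 with an estimated correlation). The list mean was higher on all 3 FoxO1 +/- arrays, and 0 members passed over the list alone. The examples were Chil4 (0.69, SE 0.24), Ms4a7 (0.35, SE 0.13) and the lysozyme gene Lyz2 (0.25, SE 0.10). Of 39 measured cytokine and chemokine genes, 29 had higher values, with a median of 0.16 (camera adjusted p 0.0429, adjusted p = 0.957 with an estimated correlation). Lif (1.17, SE 0.19) was the 1 member past 0.05 adjusted over the list alone, Il1f6 differed by 1.04 (SE 0.38) and the chemokine gene Cxcl14 by -0.47 (SE 0.15). Of 27 measured T and NK lymphocyte genes, 21 had lower values, with a median of -0.24 (camera adjusted p 0.0153, adjusted p = 0.957 with an estimated correlation). Cd247 differed by -0.33 (SE 0.16), Cd8a by -0.45 (SE 0.23) and Foxp3, of regulatory T cells, by 0.20 (SE 0.10). Of 36 measured cell cycle genes, 34 had lower values, with a median of -0.08 (camera adjusted p 0.00236, adjusted p = 0.957 with an estimated correlation). The replication genes Mcm5 and Mcm2 both differed by -0.24 (SE 0.10 and 0.12) and Kif23 by -0.16 (SE 0.10), and 0 members of either of these lists passed over the list alone. Single arrays ended these calls: the cytokine list lost its call without WT replicate 1 (adjusted p 0.872) or FoxO1 +/- replicate 1 (0.258), the cell cycle list without WT replicate 1 (0.102), WT replicate 2 (0.468) or FoxO1 +/- replicate 1 (0.440), and the lymphocyte list without WT replicate 3 (0.554), FoxO1 +/- replicate 2 (0.281) or FoxO1 +/- replicate 3 (0.135). The cytokine median was 0.087 without WT replicate 1, 0.13 without FoxO1 +/- replicate 1 and 0.32 without WT replicate 2. The cell cycle median was -0.072 without WT replicate 1. With normexp background correction the monocyte and macrophage list and the lymphocyte list lost their call (camera adjusted p 0.0765 for both). The cytokine list lost its call without a filter on dim probes (0.124), with its median still 0.16. With slide row as a block, or within slide row 1, the genotype difference rests on FoxO1 +/- replicate 1 alone against the 3 WT arrays, because row 2 held no WT array, and that single sample is assumed to vary like the others. With the block, the endothelial median was 0.06 (camera adjusted p 0.288), the lymphocyte median 0.04 (0.128), the cytokine median 0.29 and the cell cycle median -0.28, and within row 1 they were 0.09, 0.07, 0.29 and -0.27.

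The other 23 lists did not pass with the preset correlation in the main setting. Some did when a single array was left out. The smallest camera adjusted p was then 1.18e-09 for hypoxia and glycolysis, 2.765e-06 for erythrocyte and platelet, 1.93e-05 for neutrophil and 2.01e-05 for interferon response genes. The 33 measured FoxO1 target genes had 15 members higher and 18 lower, with a median of -0.01 (camera adjusted p 0.825). Among them, the mitochondrial superoxide dismutase gene Sod2 differed by 0.26 (SE 0.07), Bcl6 by 0.23 (SE 0.08) and Selenop by 0.18 (SE 0.09), against 0.15 for Sod2 and 0.049 for Selenop with quantile normalization. The insulin and PI3K signalling list had a median of 0.02, with Sgk1 at -0.31 (SE 0.13), and the antioxidant list a median of 0.08, with Nqo1 at -0.36 (SE 0.14). In the growth factor list, with a median of 0.03, 2 members passed 0.05 adjusted over the list alone: Fgf2 at 0.85 (SE 0.15, limma adjusted p 0.369 over all genes) and Angpt1, a ligand of the Tie2 receptor, at 0.42 (SE 0.08). With normexp background correction, whose offset shrinks differences of dim genes, Fgf2 differed by 0.48. In the Notch signalling list, with a median of 0.00, the receptor gene Notch1 passed over the list alone at 0.99 (SE 0.20, limma adjusted p 0.415 over all genes) and Mfng differed by 0.47 (SE 0.12). A second Notch1 probe, with a mean level of -5.16 against 0.16 for the first, differed by 0.13 (SE 0.10). Also past 0.05 over their list alone were H2-Oa (0.50, SE 0.09) in the dendritic cell and MHC class II list, whose median was 0.04, Trpm1 (1.05, SE 0.22) in the melanocyte list, and Kcnj8 (0.73, SE 0.15) in the smooth muscle and pericyte list, whose median was -0.03. The melanocyte list had a median of 0.06 and a mean of -0.21, and its pigment genes Pmel (-0.96, SE 0.32) and Tyrp1 (-1.06, SE 0.41) went the other way from Trpm1.

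Keratinocyte lists had medians of 0.08 for wound-edge genes, -0.06 for basal and hemidesmosome genes and 0.21 for epidermal differentiation genes, with camera adjusted p-values of 0.825, 0.109 and 0.304. When single arrays were left out, these medians ran from -0.08 to 0.19, from -0.21 to 0.015 and from 0.0041 to 0.34, each lowest without FoxO1 +/- replicate 3. Krt16 and Krt6a, keratins of activated keratinocytes, differed by 0.00 (SE 0.17) and -0.23 (SE 0.25), Krt17 by -0.61 (SE 0.27) and Cst6 by -0.87 (SE 0.28). Leaving out single arrays gave -0.15 to 0.14 for Krt16, -0.44 to 0.0015 for Krt6a, -0.79 to -0.31 for Krt17 and -1.20 to -0.63 for Cst6. Collagen and matrix genes had a median of 0.10 (camera adjusted p 0.0573), with Bgn at 0.25 (SE 0.08), Col1a1 at 0.06 (SE 0.09, and -0.08 with quantile normalization) and Col3a1 at 0.16 (SE 0.09, and 0.029 with quantile normalization). Matrix proteases and their inhibitors had a median of 0.09, with Timp4 at 0.80 (SE 0.25), fibroblast genes one of 0.08, with Gsn at 0.38 (SE 0.15, and 0.22 with quantile normalization), and Acta2, the actin gene of myofibroblasts, differed by 0.04 (SE 0.11). Medians were 0.12 for neutrophil genes, with Camp at 0.70 (SE 0.25), Mpo at 0.64 (SE 0.31) and Cd177 at -1.10 (SE 0.68), 0.23 for mast cell genes, 0.02 for B and plasma cell genes, 0.35 for erythrocyte and platelet genes and -0.08 for interferon response genes. They were 0.09 for hypoxia and glycolysis genes, with Vegfa at 0.28 (SE 0.16), 0.02 for immediate early and heat shock genes, 0.07 for nerve and Schwann cell genes, with Egr2 at -0.43 (SE 0.12), and 0.05 for skeletal muscle genes. The neutrophil median ran from -0.058 without WT replicate 1 to 0.34 without WT replicate 2, Mpo from 0.36 to 1.00 and Cd177 from -1.80 to -0.58 when single arrays were left out. In the same way the mast cell median ran from -0.0042 without WT replicate 2 to 0.34, and that of erythrocyte and platelet genes from 0.10 to 0.58. The hypoxia and glycolysis median ran from 0.020 without WT replicate 1 to 0.24 without WT replicate 2. Vegfa ran from 0.15 to 0.46 across the same 2 fits. The list means of skeletal muscle varied within each genotype, from -0.83 to 0.73 on the WT arrays and from -0.82 to 0.55 on the FoxO1 +/- arrays. The cytokine genes Il6, Tnf and Ccl2 differed by 0.77 (SE 0.47), 0.65 (SE 0.30) and 0.47 (SE 0.34), and Tgfb1 by 0.08 (SE 0.10), with limma adjusted p-values of 0.826 to 0.966. With single arrays left out, Il6 ran from 0.38 to 1.18, Tnf from 0.46 to 1.01 and Ccl2 from 0.23 to 0.85.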

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

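The probes below were singled out after their values were seen, because a fit over all 37898 kept probes uses 16440 probes without a gene symbol that the comparisons above leave out. In that fit 9 probes passed limma's adjusted p of 0.05, of which 5 had no symbol, all 5 with higher signal in FoxO1 +/- wounds than in the WT controls. Probe A_30_P01031267, for an interval on the forward strand of chromosome 17 (87483814 to 87493039, mm9 as the array design gives it), differed by 1.96 (SE 0.13, adjusted p 0.0227) and was well above background on all 6 arrays. Probe A_30_P01027126, for an interval on the forward strand of chromosome 12 (112223388 to 112223755), differed by 1.98 (SE 0.15, adjusted p 0.0364). Probe A_30_P01031135, for an interval on the reverse strand of chromosome 13 (81773237 to 81783062), differed by 1.54 (SE 0.10, adjusted p 0.0227). Of the 2 that carry only an Ensembl transcript identifier, A_55_P2127421 differed by 1.48 (SE 0.10, adjusted p 0.0311), and A_55_P1993775, not well above background on any WT array, was at least 6.20-fold higher (adjusted p 0.0131). The 4 with a symbol were the probes of Vmn1r227 and Defb42, described above, a probe of Tmem108, at least 1.16-fold lower and not well above background on any FoxO1 +/- array, and a probe of Gm17019, at least 2.21-fold higher and not well above background on any WT array. The genes near these intervals were not analysed here. The fit over all kept probes was made in the main setting only. How the calls of probes without a symbol depend on the processing or on single arrays was not tested.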

How the results depend on the processing

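Fits within slide row 1, over all kept probes and without both WT replicates 1 and 2 were chosen after seeing the data. The fits with slide row as a block and within row 1 take the genotype difference from FoxO1 +/- replicate 1 alone, so their calls describe that array against the WT arrays. The fit without WT replicates 1 and 2 has WT replicate 3 alone as its WT arm, so its counts and calls describe that array, assumed to vary like the others. The normexp offset by construction shrinks differences of dim genes, and so lowers counts at 2-fold. Beyond that, the cause of the other changes was not tested. The Foxo1 difference stayed below 0 and short of the adjusted threshold in every alternative: it ran from -0.60 to -0.35 when single arrays were left out, was -0.51 with slide row as a block and within row 1, and was -0.69 with the mean of both probes and -0.74 without WT replicates 1 and 2. The count past an adjusted p of 0.05, 1 in the main setting, was 2 with quantile normalization or median centring, 0 with the percentile over detected probes, with only probes above background on all 6 arrays, or with an intensity trend and robust fit, 3 without a filter on dim probes, 4 with array weights, 7 with slide row as a block (1 higher and 6 lower), 5 within slide row 1, 3 without WT replicates 1 and 2, 9 over all kept probes, and 5 at an adjusted p of 0.1. It was 0 to 28 when single arrays were left out. Where it was 0, between 678 and 1085 genes had an unadjusted p under 0.05. Vmn1r227 had an adjusted p between 0.0134 and 0.563 where it was tested. The count at an unadjusted p under 0.05 and 2-fold, 117, was 61 with normexp, 191 without a filter, 323 without WT replicates 1 and 2 (102 higher and 221 lower), and 92 to 234 when single arrays were left out. The count of lists, 8, was 0 with an estimated correlation and 0 with fry, 12 without WT replicates 1 and 2, and 7 to 13 when single arrays were left out.

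No correlation of same-numbered animals' deviations was above 0 (-0.07, -0.14 and -0.30), and no array correlated best with its own number. These few values, from deviations centred within groups of 3 arrays, gave no sign of a pairing by number but cannot exclude one. With the animal number as a block, 0 genes passed the adjusted p, 793 had an unadjusted p under 0.05, 119 also differed 2-fold, 9 lists passed, and Foxo1 differed by -0.48.

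The direction of a list's camera test turned, with a call in the main setting or in the alternative, for skeletal muscle (median 0.61 with slide row as a block and within row 1, and -0.40 to 0.47 when single arrays were left out), interferon response (0.28 in both row fits, and -0.26 to 0.15), erythrocytes and platelets (-0.21 in both), T and NK lymphocytes (0.042 with the block, 0.068 within row 1, and -0.42 to 0.0021 when single arrays were left out), cell cycle (0.13 against WT replicate 3 alone) and FoxO1 targets. The FoxO1 target list, not called and with its camera direction above 0 in the main setting, was called lower there (median -0.10). Of the 31 list medians, 21 changed sign under some alternative, 17 of them when a single array was left out. Among the 8 called lists these were T and NK lymphocytes and cell cycle, whose median was 0.00074 without WT replicate 2. Of 176 alternative results of the 8 called lists, 141 stayed called the same way, 31 lost the call and 4 turned. Of 506 alternative results of the 23 lists not called, 440 were the same and 16 moved without a call. The others gained a call, 40 in the same direction and 10 in the other. Of 2554 alternative results of 128 named genes, 2315 were the same, 214 moved by more than the standard error, 14 passed the adjusted threshold that the gene had missed, and 11, all of Vmn1r227, lost the call. No named gene past the threshold changed sign, whereas 15 named genes short of it changed sign under some alternative. Signal over background limits dim genes most on FoxO1 +/- replicate 3.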

Other observations

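The tests in this part were chosen after the results they bear on were seen, except the test of the cholesterol list and that of enrichment on the chromosome of Foxo1, which were set before their own results were known. Genes of cholesterol synthesis and uptake, a list written down after 2 of its members, Hsd17b7 among them, had been seen among the lower genes, had lower values in FoxO1 +/- wounds. In the main setting all 22 measured members were lower, 13 of them at an unadjusted p under 0.05, with a median log2 difference of -0.38. Besides Hsd17b7 (-0.79, SE 0.12), the lanosterol synthase gene Lss differed by -0.76 (SE 0.16), Cyp51 by -0.54 (SE 0.12) and Idi1 by -0.53 (SE 0.12). None passed limma's adjusted threshold over all genes, with adjusted p-values of 0.313 to 1.00. The camera p of the list alone was 6.21e-18 with the preset correlation and p = 0.0513 with an estimated one. Without the 2 genes that prompted the list, the 20 others were all lower in the main setting, with a median of -0.36 and a camera p = 0.0625 with an estimated correlation. That every member was lower did not hold throughout: of the 22, 21 were lower with normexp and 19 to 22 when single arrays were left out, with medians of -0.45 to -0.31, and members such as Stard4 (-0.0044, SE 0.15) and Sc5d (-0.026, SE 0.18) differed by far less than their SE.

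One hypothesis is that genotype alters sterol synthesis genes in the wound, along with the lower sebaceous gland list. The mean difference of the cholesterol list was -0.37 against a pooled SD of 0.12, and all 3 FoxO1 +/- arrays (-0.29, -0.26 and -0.01) lay below all 3 WT arrays (0.23, 0.09 and 0.24). The largest difference among the other 9 splits of the arrays was 0.307 in size, and the smallest exact p for 3 against 3 arrays is 0.1. Across the scaling alternatives the median ran from -0.39 to -0.35. None of the list's members is in the sebaceous gland list, but sebaceous cells make sterols, so less gland tissue in the FoxO1 +/- biopsies may give the same values and stays open.

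The lower hair follicle list is a candidate for the content of a single biopsy. Without WT replicate 1 its mean difference was -0.13, within the pooled SD of 0.17 of the other arrays, against -1.10 with all 6 arrays. This is consistent with more growing hair in the WT replicate 1 sample. A genotype difference in the hair follicle is not shown by these arrays and stays untested beyond them.

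The higher adipocyte list did not rest on WT replicate 2 alone: without that array its mean difference was 0.32, above the pooled SD of 0.13, against 0.57 with it. More subcutaneous tissue of every kind in the FoxO1 +/- biopsies cannot be told apart from a genotype difference, because the skeletal muscle list differed by 0.0018 with a pooled SD of 0.76. A genotype difference in fat cells also stays open as a hypothesis.

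The olfactory, vomeronasal and defensin genes past an adjusted p of 0.1 were Vmn1r227, Defb42, Olfr1211 and Olfr122. Olfr1500 and Olfr141, also named above, had limma adjusted p-values of 0.173 and 0.190, and the test of the 4 genes' positions left them out. A common lift of olfactory and vomeronasal receptor genes in the FoxO1 +/- arrays is argued against by the 314 measured ones. Their median difference was -0.016 (95% bootstrap interval -0.043 to 0.013). At an unadjusted limma p under 0.05, 16 were higher and 23 lower, against 562 higher and 464 lower of all 16408 genes. The receptor genes were taken as a family that passed the background filter, and not by dimness. A lift limited to the dimmest probes was therefore not tested. Linkage of the 4 genes themselves to the Foxo1 locus is argued against by their positions, on chromosomes 17, 14, 2 and 17, since 0 of 4 lie on chromosome 3 with Foxo1. For the wider set, genomic material linked to the Foxo1 locus stays open: 11 of 171 genes with an unadjusted p under 0.01 and at least 1.5-fold lay on chromosome 3, where 8.48 would by chance, an odds ratio of 1.32 (95% interval 0.644 to 2.44, two-sided Fisher's exact p 0.372). Cross-hybridisation of these probes was not tested.

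For the counts, the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1 gene past the adjusted p against at most 0 in the others, 117 genes at an unadjusted p and 2-fold against at most 77, and in each case 1 of the 10 splits reached the real count. At an unadjusted p under 0.05 alone, the real split gave 1026 genes and the highest other 1319, and 4 of the 10 splits, the real one included, gave at least as many. For the gene lists the real split gave 8 and the highest other 15, and 10 of the 10 splits gave as many as the real one.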
